A study of Pyrus ussuriensis with 15 samples.

How the data were processed

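Messenger RNA was sequenced from *Pyrus ussuriensis* Maxim, an Asian pear, while adventitious roots formed on shoots kept in tissue culture. Adventitious roots are roots that arise from stem or shoot tissue and not from the seedling root. Per the labels' protocols, buds subcultured for 25 days were moved to root induction medium with 0.5 mg/L IBA (indole-3-butyric acid, an auxin), 30 g/L sucrose and 7.5 g agar at pH 6.0, and libraries were built with an Illumina TruSeq kit from 1 µg of total RNA. Samples were grouped by the development stage in the labels, which gives day 0, 3, 6, 9 and 12 with 3 libraries each. The series title speaks of 4 stages while its design text lists these 5 days, and the tissue label reads adventitious roots on each day, day 0 included. The labels number the replicates and do not say that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

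The authors deposited 1 table for the whole series, with the position, strand and length of 44681 gene models and, per library, a read count and an FPKM value. The count columns hold whole numbers per model with no normalization, per the file headers and the values. The FPKM columns are the authors' normalization of those counts to model length and library total: recomputing them from the counts gave back 97.58% of the 492150 values above 0 within a relative tolerance of 1e-04, and the rest belonged to models of at most 7032 bases. Reads were compared with the *Pyrus bretschneideri* genome, per the series' design text, and HISAT is named as a tool per the submitters' processing notes. The versions of HISAT and of the genome, the counting program, its use of strand and its treatment of reads that fit several places are not given in the sources used here. Reads of 1 pear species were thus placed on the genome of another, and models with near-identical copies may have exchanged or lost reads. Of the models, 42812 have IDs that start with Pbr, and all of their lengths are multiples of 3, so these are coding lengths without untranslated regions. The other 1869 models carry a different prefix, and 34.46% of their lengths are multiples of 3. No row lacked a gene model ID, and each column of counts matched 1 sample by its title.

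The count test was edgeR 4.0.16 in R 4.3.3. Models were kept by filterByExpr with the 5 days as groups, which left 29134 models, while 7148 models had no count in any library. Library sizes were scaled by TMM, dispersions were estimated over all 15 libraries, and glmQLFit and glmQLFTest compared each later day with day 0 and each day from day 6 on with the sampled day before it. An F-test over the 4 day coefficients covered the whole course. The fit had 10 residual degrees of freedom and 3.26 prior degrees of freedom, with a common biological coefficient of variation of 22.98%. P-values were adjusted by Benjamini-Hochberg within each comparison and called at an FDR under 0.05. Counts with an absolute log2 fold change of at least 1 stand beside the full counts. Expression levels are TMM-scaled CPM, the count of a model relative to the scaled total of its library, with the SD over 3 libraries, and the standard error of a log2 fold change was its size divided by the square root of its F value. Principal components were taken of log2 CPM with a prior count of 2.

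Total counts ran from 11953240 to 17878524 per library. A group with 0 counts in all 3 libraries was set to a floor of 3 counts over the group when a fold was computed, which makes that fold a lower bound that covers counting error only. The test was checked on simulated counts with the real libraries' means and sizes. In the simulated day 3 against day 0 comparison of 29134 models, 100 models were changed 2-fold and 100 models 4-fold. Of these, 35% and 66% were recovered, and 8 of 109 called models had not been changed.

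The tests, their samples and the alternatives were set before the data were examined, except where stated. The rule for named genes, also set then, took for each later day the 5 largest rises and the 5 largest falls among called models with a mean log2 CPM of at least 1 whose 3 libraries all lay beyond those of day 0. The deposited table pairs no ID with a description and no table of gene names was used here, so at most 2 IDs per direction are printed. They are the models the rule took on the most days, with ties settled by the largest change, a narrowing that the original rule did not contain. Gene lists for hormone, cell cycle, wall and other functions had been written as patterns on gene descriptions; with no descriptions they were not tested. Plans for a table of extended gene ends did not apply, since the table holds expression values.

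Groups of models were instead formed from the table's own columns after it had been seen. They are the models without the Pbr prefix, models in 1 block (length equal to the span on the scaffold), the models in the lowest and highest 25% of length, and the 10% with the highest mean log2 CPM. Their shares of called and of higher models were compared with those of all other tested models by two-sided Fisher's exact tests, adjusted over 30 tests, across genes, which are not independent replicates. Also chosen after seeing the data were the classes over consecutive days, the counts of models switched between 0 and at least 10 counts, the correlation of change with length, the test of neighbouring models and the regions. For the length trend, each library's deviation from the model means was smoothed against log2 length by lowess with a span of 0.3, the smoothed trend was added to the fit as an offset, and all counts were computed again. In the simulated day 9 comparison with a planted length trend over 29134 models, 4506 models were called before this correction and 112 after it, and 52% of the changed models were recovered after it. Neighbouring models were adjacent tested models on 1 scaffold, and the number of neighbours that both changed at least 2-fold in the same direction was compared with 1000 shuffles of the changes over all models. Listed models that were not tested were passed over, so a region need not hold a change of each model listed in its span.

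The alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in edgeR, no filter beyond a count above 0, the replicate number as a block, a fit on only the 2 days compared, and leaving out each library of the days compared. Length-corrected fits and fits without the day 6 libraries were added after seeing the data. Replicate pairs were compared by chi-square, which gave between 4.20 and 45.4 per model, so no pair agreed within sampling noise and each library counted as 1 replicate.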

Results

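Messenger RNA of *Pyrus ussuriensis* was measured on 5 days of adventitious root development, with 3 libraries on each of day 0, 3, 6, 9 and 12. The depth ran from 11953240 counts in day 9 replicate 2 to 17878524 counts in day 12 replicate 3. Of 44681 gene models, 29134 were tested. The first principal component of log2 CPM held 31.3% of the variance and set day 9 at one end, with scores from 100.7 to 121, and day 0 at the other, with scores from -63.9 to -58.9. The second held 25.2% and set day 12, with scores from 106.4 to 111, apart from all other libraries, which lay between -43.4 and -5.43. Day 6 replicate 2, at -38.6 on the first component, lay nearest the day 3 libraries, whereas day 6 replicates 1 and 3 lay at 0.813 and 8.96.

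**Figure D1:**
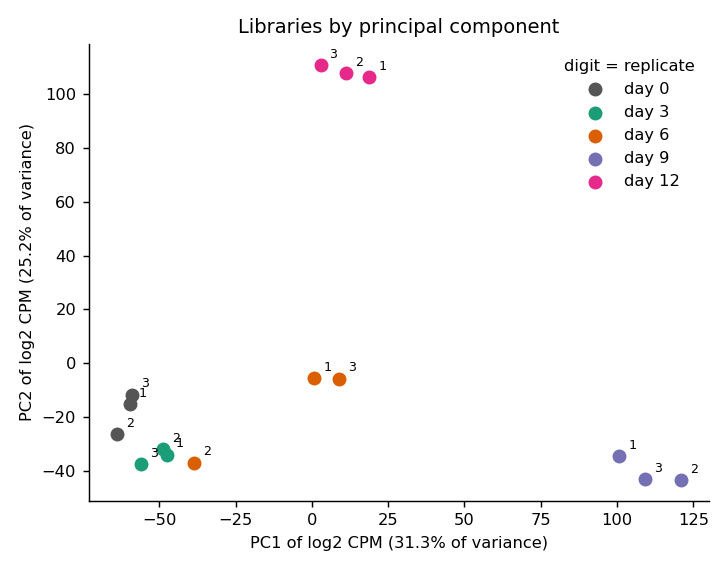
Each point is a library, placed by its scores on the first principal component (horizontal axis, 31.3% of variance) and the second (vertical axis, 25.2%) of log2 CPM, with colour for the day and a digit for the replicate. Day 9 libraries lie at 100.7 to 121 on the horizontal axis and day 12 libraries at 106.4 to 111 on the vertical axis, while day 6 replicate 2 lies by the day 3 libraries.

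The comparison of day 3 with day 0 asked which genes had changed soon after the move to root induction medium. Pbr013951.1, a model with a coding length of 522 bases on the minus strand of scaffold205.0 (434966 to 435854), rose from 0.127 ± 0.219 CPM at day 0 to 12.4 ± 5.06 CPM at day 3 (SD, n = 3 each). Its 6 counts at day 0 all came from replicate 1, and it had 99 to 271 counts per library at day 3. Pbr020853.1, with a coding length of 1722 bases on the minus strand of scaffold31.0 (722954 to 742879), fell from 859 ± 395 to 31.3 ± 24.0 CPM (SD, n = 3 each). Pbr019916.1, with a coding length of 2979 bases on the plus strand of scaffold3.0 (2285882 to 2292420), fell from 75.9 ± 35.4 to 6.87 ± 2.99 CPM (SD, n = 3 each). Pbr011559.1, with a coding length of 963 bases on the plus strand of scaffold181.0 (133469 to 134773), rose from 0.307 ± 0.0403 to 1.57 ± 0.725 CPM (SD, n = 3 each). What these 4 models encode was not given with the table.

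At day 3, the log2 fold changes against day 0 were 6.48 ± 0.721 for Pbr013951.1 (SE, adjusted p = 0.000961), 2.32 ± 0.657 for Pbr011559.1 (adjusted p = 0.0432), -4.78 ± 1.15 for Pbr020853.1 (adjusted p = 0.0232) and -3.46 ± 0.570 for Pbr019916.1 (adjusted p = 0.00437), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 1301 models were higher and 1427 lower at day 3, and 548 and 661 of these differed at least 2-fold. The 10% of models with the highest mean expression were called more often than the rest, with 16.3% of 2914 models called against 8.59% of the others (Fisher's exact test across genes, adjusted p = 1.1e-35), but 2.30% of them against 4.36% of the others were called at 2-fold or more. The 1694 tested models without the Pbr prefix were called less often, 4.31% against 9.68% (adjusted p = 2.67e-15), and 2.13% against 4.27% at 2-fold or more. They were also called less often at day 6 (4.78% against 9.85%) and day 12 (15.2% against 23.0%). At day 9 this did not hold, with 51.2% called against 49.6% of the others, and 31.6% against 22.8% at 2-fold or more. The count of 2728 called models depended on single libraries: it was 1052 without day 0 replicate 2, 1340 without day 0 replicate 3, 1488 without day 3 replicate 1, 1004 without day 3 replicate 2 and 1488 without day 3 replicate 3, against 4161 with DESeq2 and 5014 without the day 6 libraries in the fit. The calls of Pbr011559.1 and Pbr020853.1 were each lost in 5 of the 6 fits that left out a day 0 or day 3 library, with day 0 replicate 1 the exception for Pbr020853.1 and day 3 replicate 1 for Pbr011559.1. Without day 0 replicate 1, which held all day 0 counts of Pbr013951.1, its fitted log2 change was 10.55 at day 3, 10.54 at day 6, 11.15 at day 9 and 11.09 at day 12, values that depend on the prior count.

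**Figure D2:**
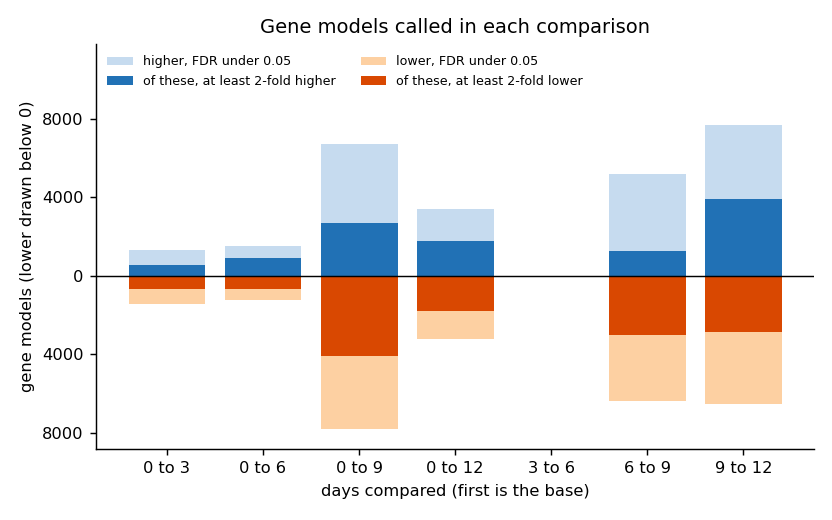
Bars give the number of gene models called at an FDR under 0.05 in each comparison, higher models above 0 and lower models below it, with the darker part for changes of at least 2-fold. Comparisons with day 9 have the tallest bars, from 11533 to 14484 models, and day 6 against day 3 has none.

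At day 6, runs of neighbouring models on 3 scaffolds were higher than at day 0. On scaffold563.0, 5 models between 172066 and 221755 were 2.14 to 4.85 higher on the log2 scale. On scaffold616.0, 5 models between 50719 and 129399, all on the plus strand, were 2.63 to 4.34 higher. On scaffold46.0, 5 models between 824586 and 894051, all on the minus strand, were 1.09 to 1.63 higher, and 4 of these 5 were already called higher at day 3. By day 12 none of the models on scaffold563.0 was called higher and 1 was lower, while on scaffold616.0 1 of the 5 was called higher. On scaffold46.0, 3 of the 5 were called lower than day 0 at day 12 and none higher. These regions were chosen after their values had been seen. Their spans list 6, 7 and 10 models on scaffold563.0, scaffold616.0 and scaffold46.0, and the models beyond these 5 each were not tested. Some of the models on scaffold563.0 have equal spans, such as 185717 to 186253 and 191326 to 191862, so copies that share reads are possible there. Without day 0 replicate 2, 2 of the 5 models on scaffold46.0, 2 on scaffold563.0 and 4 on scaffold616.0 kept their call at day 6, and all 15 kept their direction.

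Pbr013951.1 was at 12.2 ± 5.88 CPM at day 6 (SD, n = 3), a log2 fold change from day 0 of 6.46 ± 0.721 (SE, adjusted p = 0.000553). Pbr019916.1 was at 1.51 ± 1.72 CPM (SD, n = 3), lower by a log2 fold change of -5.64 ± 0.661 (SE, adjusted p = 0.000682). The other two models varied widely between the day 6 libraries: Pbr020853.1 had 101.6, 23.4 and 1.27 CPM in replicates 1, 2 and 3, and Pbr011559.1 had 3.37, 1.48 and 7.54 CPM. Their log2 fold changes were -4.36 ± 1.13 (SE, adjusted p = 0.0286) and 3.73 ± 0.596 (SE, adjusted p = 0.0027). Over all models, 1543 were higher and 1242 lower at day 6, with 888 and 682 at least 2-fold. Models in 1 block rose more often among their calls, with 427 higher and 227 lower, or 65.3% higher against 52.4% of the called others (Fisher's exact test across genes, adjusted p = 1.65e-08). At day 12 the order was reversed, with 47.0% higher against 52.6% (same test, adjusted p = 0.000572).

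The 3 day 6 libraries correlated with each other at 0.939 to 0.948 across genes (Pearson's r of log2 CPM), below the 0.963 to 0.985 within other days. The test shares 1 estimate of the spread over all days, so its day 6 p-values may be too small. The count of 2785 models fell to 1110 without day 0 replicate 2 and rose to 4382 without day 6 replicate 1, and a fit on only the days 0 and 6 called 25 models, among which Pbr013951.1, Pbr011559.1, Pbr020853.1 and Pbr019916.1 were not. The call of Pbr020853.1 at day 6 was also lost without day 0 replicate 2, day 0 replicate 3 or day 6 replicate 2. Single day 6 libraries moved the size of 3 changes: Pbr020853.1 was at a log2 change of -6.13 without replicate 1 and -3.76 without replicate 3, Pbr019916.1 at -7.20 without replicate 2 and Pbr011559.1 at 2.94 without replicate 3.

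**Figure D3:**
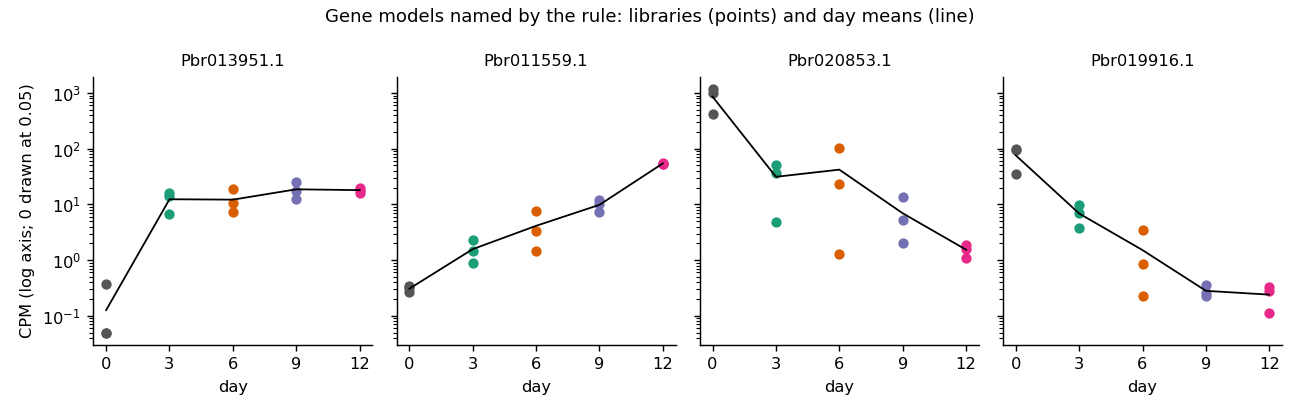
Each point is a library's TMM-scaled CPM (log axis, 0 drawn at 0.05) against the day for the 4 named models, and the line joins the day means. Pbr011559.1 goes from a mean of 0.307 CPM at day 0 to 54.5 CPM at day 12 and Pbr020853.1 from 859 to 1.54 CPM, with widely spread day 6 libraries.

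Day 9 set the largest number of models apart from day 0, 6708 higher and 7776 lower, of which 2707 and 4077 differed at least 2-fold. More short models were called higher than lower, and more long models lower than higher, though many of both were not called. Among the 7322 tested models of at most 702 bases, 2872 were higher, 831 lower and 3619 not called, whereas among the 7299 models of at least 1758 bases 539 were higher, 3819 lower and 2941 not called. The median log2 change was 0.464 over the 2914 shortest models, with quartiles of -0.163 and 0.929, and -0.717 over the 2914 longest, with quartiles of -1.26 and -0.245. Models in 1 block were higher in 59.8% of their calls against 43.2% for the others (Fisher's exact test across genes, adjusted p = 3.17e-54), and with the length trend removed these shares were 53.5% and 46.6%.

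The Spearman correlation of the day 9 change with length across the 29134 models was -0.376, and each of the 3 libraries gave a like value against the day 0 mean, from -0.396 to -0.340. It was 0.0789 at day 3, 0.00483 at day 6 and -0.00257 at day 12, and genes are not independent replicates. The mean model length weighted by counts was 1284 ± 9.16 bases at day 9 and 1572 ± 34.6 bases at day 0 (SD, n = 3 each). With the trend removed from each library, 12329 models were called at day 9, of which 9964 were called in the same direction before. The short models then had 1396 higher and 1444 lower calls and the long models 1632 and 1844. The 4354 models whose call was lost had a median absolute log2 change of 0.63 before and 0.227 after the removal, and another 166 models were called in the opposite direction after it.

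**Figure D4:**
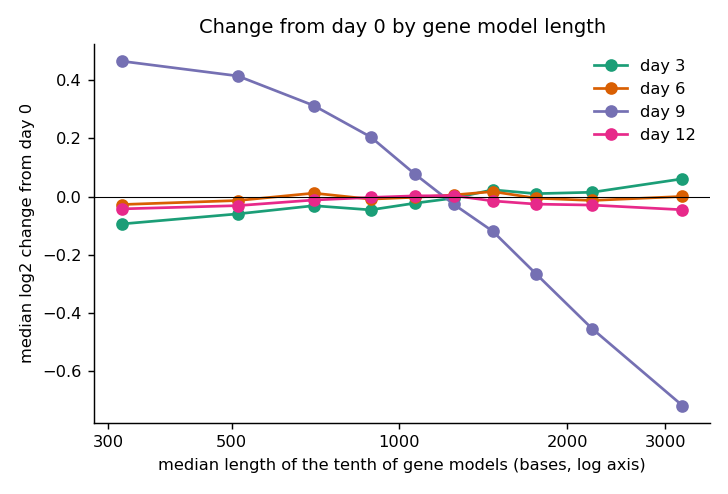
The median log2 change from day 0 (vertical axis) is plotted against the median length in bases (log axis) of 10 equal groups of tested models, with 1 line per later day. At day 9 the medians run from 0.464 for the shortest group to -0.717 for the longest, while those of day 3, day 6 and day 12 stay between -0.094 and 0.0607.

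Of 10 models listed on scaffold705.0 between 52399 and 134143, 7 were tested. These 7 neighbouring models were all lower at day 9, by log2 changes from -6.84 to -1.45. The median over these 7 was -3.92 at day 9 against 0.0227 at day 3, 0.0114 at day 6 and -0.264 at day 12, and 1 model of the 7 was called lower on each of those days. In the fits that left out a day 0 or day 9 library, 6 or 7 of the models kept their call, and 6 did with the length trend removed. The 5 models of scaffold563.0 were also higher at day 9, with a median of 3.12, though 3 of them were called without day 0 replicate 2, 3 without day 9 replicate 2 and 3 with the length trend removed. On scaffold841.0, 17 models are listed between 3273 and 169529 and 5 were tested. These 5 were higher by 1.12 to 3.36 and were called in each fit that left out a library. Some of them have equal spans on opposite strands, such as 3273 to 4884 and 167918 to 169529, so copies that share reads are possible. On scaffold48.0, 5 models between 343682 and 379223, all on the minus strand, were higher by 1.02 to 2.80, and 4 or 5 of them were called with a library left out.

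**Figure D5:**
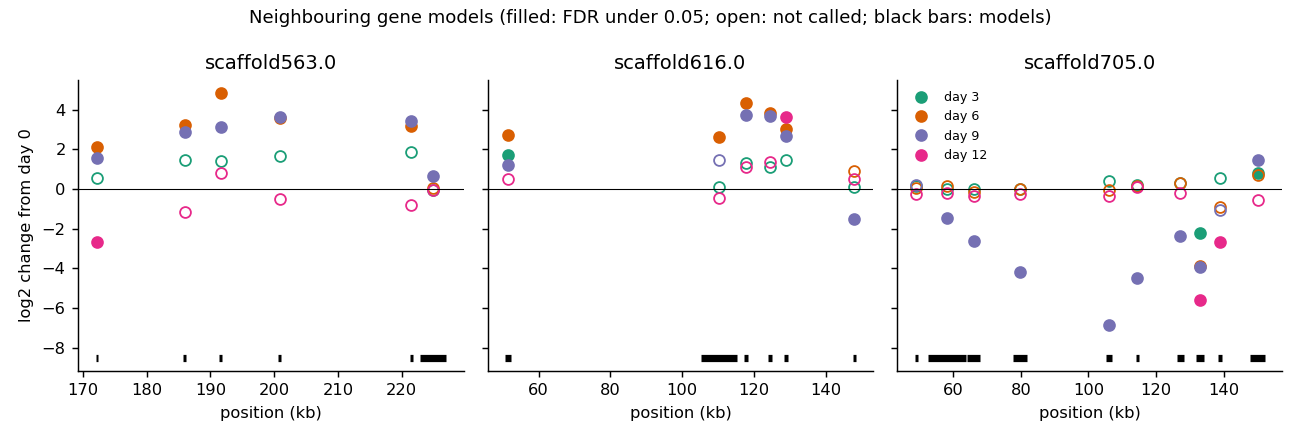
The log2 change from day 0 of each gene model (vertical axis) is drawn at its position in kb on 3 scaffolds, with colour for the day, filled points for an FDR under 0.05 and black bars for the models. The 5 models on scaffold563.0 and 5 models on scaffold616.0 are higher at day 6, 5 and 4 of them also at day 9, and 7 models on scaffold705.0 are lower at day 9.

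At day 9, Pbr011559.1 was at 9.83 ± 2.32 CPM and Pbr013951.1 at 18.7 ± 6.47 CPM (SD, n = 3 each), log2 fold changes of 4.97 ± 0.575 (SE, adjusted p = 1.5e-05) and 7.07 ± 0.716 (SE, adjusted p = 5.03e-06). Pbr020853.1 was at 6.93 ± 5.87 CPM and Pbr019916.1 at 0.281 ± 0.0697 CPM (SD, n = 3 each), log2 fold changes of -6.92 ± 1.29 (SE, adjusted p = 0.000662) and -8.06 ± 0.818 (SE, adjusted p = 5.17e-06). Pbr020853.1 was at a log2 change of -7.83 without day 9 replicate 3, and Pbr019916.1 at -7.47 with the length trend removed and -7.42 with the replicate block added to that fit. Against day 6, Pbr011559.1 was called, with a log2 change of 1.24 ± 0.414 (SE, adjusted p = 0.0295), and Pbr013951.1 (adjusted p = 0.287), Pbr020853.1 (adjusted p = 0.0831) and Pbr019916.1 (adjusted p = 0.0677) were not. At day 9, 28 models had no count in any library after at least 10 counts in each day 0 library, and the largest of these falls was at least 87.4-fold lower, while 2 models did the opposite.

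At day 12, Pbr011559.1 rose to 54.5 ± 1.59 CPM (SD, n = 3), the largest rise named on that day, with a log2 fold change from day 0 of 7.43 ± 0.573 (SE, adjusted p = 1.85e-06). Pbr020853.1 was at 1.54 ± 0.401 CPM (SD, n = 3), a log2 fold change of -9.13 ± 1.46 (SE, adjusted p = 0.00059). Pbr013951.1 was at 18.0 ± 1.74 CPM and Pbr019916.1 at 0.240 ± 0.112 CPM (SD, n = 3 each), with log2 fold changes of 7.02 ± 0.715 (SE, adjusted p = 1.8e-05) and -8.27 ± 0.811 (SE, adjusted p = 1.32e-05). At day 12, 40 models had at least 10 counts in each library after none in any day 0 library, and 39 of them were called. The largest of these rises was at least 288-fold higher. Going the other way, 15 models had no count at day 12 after at least 10 in each day 0 library, the largest fall being at least 368-fold lower.

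On scaffold3.0, 5 neighbouring models between 1875447 and 1900784 were higher at day 12 by log2 changes from 1.51 to 5.64, and all 5 were called in each fit that left out a day 0 or day 12 library. On scaffold164.0, 9 models are listed between 597381 and 657424 and 4 were tested. These 4, all on the minus strand, were lower by -6.64 to -3.76 on the log2 scale at day 12. Their medians were -0.190 at day 3, -1.50 at day 6 and -2.52 at day 9, when 2 of the 4 were called lower. All 4 of these calls were lost without day 12 replicate 2, while the direction held. On scaffold398.0, 4 models between 215955 and 228777, all on the plus strand, were higher by 2.10 to 3.51, and 3 of them were already called higher at day 3. These 4 were called in each fit that left out a library, and the regions were again chosen after their values had been seen. Over all models, 3387 were higher and 3194 lower at day 12, with 1758 and 1813 at least 2-fold. Models without the Pbr prefix were higher in 43.0% of their calls, 111 higher and 147 lower, against 51.8% for the others (Fisher's exact test across genes, adjusted p = 0.00847). The 7 models of scaffold705.0 had 1 call at day 12 and the short and long models 48.9% and 48.2% higher calls, against 77.6% and 12.4% at day 9.

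The consecutive days asked where along the course the changes fell. From day 3 to day 6 edgeR called no model, with a smallest adjusted p of 0.127, although 4111 models had an unadjusted p under 0.05 where chance gives 1456.7, and DESeq2 called 484. Without day 6 replicate 2, edgeR called 2098 models. From day 6 to day 9, 5190 models rose and 6343 fell, 1263 and 2997 of them at least 2-fold. With the length trend removed, 3635 rose and 4496 fell, 764 and 2179 of them at least 2-fold, and of the 11533 calls 6421 kept their direction, 4984 were lost and 128 were called in the opposite direction. From day 9 to day 12, 7699 rose and 6544 fell, 3900 and 2855 of them at least 2-fold. With the length trend removed, 6441 rose and 5749 fell, and of the 14243 calls 10035 kept their direction, 4074 were lost and 134 were called in the opposite direction. From day 9 to day 12, 47 models went from no count in any day 9 library to at least 10 counts in each day 12 library, 46 of them called and the largest at least 90.9-fold higher, and 3 models did the opposite.

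Most models called from day 6 to day 9 and again from day 9 to day 12 changed in opposite directions on these steps. Day 12 was not tested against day 6, so a return to the earlier level is not shown. The number that fell and then rose was 4996, and the number that rose and then fell was 3508, while 156 rose on both steps and 141 fell on both. Independent lists of these sizes would share 1676, 1166, 1372 and 1425 models. Both steps use the day 9 libraries, so part of the excess of models with opposite steps may come from those libraries. With the length trend removed, 2321 models rose and then fell and 3441 fell and then rose. From day 6 to day 9, the models of at most 702 bases had 2582 rises and 601 falls and those of at least 1758 bases 287 rises and 3500 falls, and from day 9 to day 12 the same groups had 856 rises and 2894 falls and 3615 rises and 583 falls.

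Against day 0, 210 models were higher on all 4 later days and 317 were lower on all 4. Day 3 and day 6 shared 716 higher and 647 lower models, where independent lists would share 68.9 and 60.8. Day 9 and day 12 shared 1585 higher and 1474 lower models, where independent lists would share 779.8 and 852.5. Simulated unchanged groups called at most 0.4 models in any comparison, so their shared count of 0 gives no measure of the overlap that shared libraries add. Another 462 models were higher at day 9 and lower at day 12, and 453 the reverse. Across the 29134 models the log2 changes of day 3 and day 6 correlated at 0.692, where unchanged groups against the same controls gave 0.500, and their covariance was 0.398 against a simulated 0.0742. For day 9 and day 12 the correlation was 0.451 against 0.502 and the covariance 0.599 against 0.0747. Every one of these comparisons uses the same 3 day 0 libraries, too few to split, so part of the overlaps may come from those shared controls.

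Over the 5 days as a whole, 19158 of the 29134 tested models, or 65.8%, changed by edgeR's F-test at an FDR under 0.05, and 9976 were not called.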

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

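All tests of the length trend were chosen after the trend had been seen, though the bounds for each were set before its value was computed.

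The change from day 0 differed between day 6 and day 9 for 11533 models and between day 9 and day 12 for 14243 models, by edgeR's test of day 9 against day 6 and of day 12 against day 9, in which day 0 cancels. With the length trend removed the counts were 8131 and 12190, of which 6421 and 10035 were called in the same direction before. Day 0 is the same 3 libraries for all days. The sum of the deposited FPKM values, a column that no comparison used, was 1335767 ± 7755 at day 9 against 1155249 ± 24777 at day 0 (SD, n = 3 each), higher in each day 9 library than in any day 0 library. FPKM divides a count by model length, so this sum rises when counts move to shorter models.

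Shorter models tended to be higher and longer models lower at day 9. Without the 100 models of highest expression the rank correlation across genes was -0.3753. Dropping so few of 29134 models cannot move a rank correlation, so this value cannot decide whether a few abundant genes took the counts. The 10 most abundant models of a library held 7.07 ± 0.204% of its counts at day 9 and 5.76 ± 0.277% at day 0 (SD, n = 3 each). The tables argue against a minority of short genes, since 70.45% of the 2914 shortest models lay above 0. With the trend removed, 9964 of the 14484 day 9 calls kept their direction and 166 were called in the opposite one. Leaving out day 9 replicates 1, 2 and 3 in turn gave corrected day 9 counts 1.66, 1.501 and 1.638 times those of day 12. Of these ratios, 1.501 lies barely above the bound of 1.5 set for it. They cannot decide whether the trend was the whole source of the day 9 calls, since 1 curve was removed per library. The rank correlation was -0.5494 over the 14567 models of higher expression and -0.2675 over the 14567 of lower expression. After the removal, the 10% with the highest expression were still higher in 64.27% of their calls, against 45.59% for the others. Remaining calls may thus hold leftover trend. A length-dependent yield of the day 9 libraries, for example from RNA quality or library building, cannot be told apart from a change of the tissue at day 9, because the 3 libraries that share the trend are all the libraries of that day and the weakest of them had -0.3404. A change in the makeup of the roots at day 9 thus stays open as an untested biological explanation.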

How the results depend on the processing

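Fits with length correction and without the day 6 libraries, the length and neighbour results and the classes over 3 days were added after seeing the data. Under the alternatives, 132 counts of called models stayed within 1.5 times the reported count and 16 did not. For day 3 against day 0 (2728 models) the count was 4161 with DESeq2, 5014 without all day 6 libraries, and 1004 to 2448 with a day 0 or day 3 library left out. For day 6 against day 0 (2785 models) it was 25 in a fit on only the 2 days compared and 1110 to 4382 with a library left out, the ends being without day 0 replicate 2 and without day 6 replicate 1. For day 6 against day 3 it was 0 in the main test, 484 with DESeq2, and 0 to 2098 with a library left out, the highest without day 6 replicate 2; DESeq2 gave 4313 models an unadjusted p under 0.05 and left the adjusted p of 1785 models undefined. The number of models that rose from day 6 to day 9 and then fell (3508) was 2321 with length-corrected offsets and 2241 with length-corrected offsets and the replicate block. Smaller fits have fewer degrees of freedom. That alone does not account for the 25 models at day 6, since fits on only 2 days called 2231 models for day 3, 13935 for day 9 and 7584 for day 12 against day 0. The cause of the differences was not tested. With a library left out, counts for day 9 against day 0 ran from 12495 to 13178, for day 12 against day 0 from 4616 to 5722, for day 9 against day 6 from 9555 to 12200, for day 12 against day 9 from 11794 to 12946 and over the 5 days from 17238 to 20689.

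None of these alternatives reversed a named model, which the naming rule largely fixed, since it took models whose 3 later libraries all lay beyond those of day 0. Of the alternative values for the 4 named models, 203 kept their call and 17 lost it, all of these at day 3 or day 6. The rank correlation with length at day 9 (-0.376) was -0.280 without the filter on low counts and -0.406 in a fit on only the 2 days. The ratio of like-changed neighbours to shuffled order at day 3, 3.57 in the shorter run of shuffles used here, was 6.39 without day 3 replicate 2 and moved by less than 1.5 times in the other 53 alternatives over the 4 days. With the replicate number as a block the counts were 2405, 2513, 14282 and 6396 for day 3, 6, 9 and 12 against day 0, then 0, 11257 and 14047 for the consecutive days and 18558 over the 5 days. Whether like numbers share more than a name is not settled. Deviations of like-numbered libraries correlated above 0.1 in 2 of 30 pairs, from -0.0816 to 0.166, and 7 of the 15 libraries correlated best with their own number in another day. The like-numbered pairs of day 0 and day 6 gave the highest values, 0.133, 0.166 and 0.0914 for replicates 1, 2 and 3. The gene list tests, with their set test, pairing and correlation alternatives, were not run for want of descriptions; the pseudocount and quantile alternatives apply to normalized values and the gene end alternatives to another kind of table, so they were not run; a fit on only 2 days does not apply to the test over the 5 days. With 3 libraries a day, the simulated day 3 comparison recovered 35% of 2-fold and 66% of 4-fold changes, so an uncalled model at days 3 and 6 may still have changed 2-fold. The simulation changed 100 models by each fold, far fewer than the data called, so the shares recovered in the data may differ from these.

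Splits of the 6 libraries of a pair of days number 10, too few for a share under 0.05, so chance is not judged by them. The real and the highest other split called 2728 and 1 models for day 3 against day 0, 2785 and 331 for day 6, 14484 and 0 for day 9, 6581 and 0 for day 12, 11533 and 4 for day 9 against day 6, and 14243 and 1 for day 12 against day 9; in each, 1 of the 10 splits, the real one, reached the real count. For day 6 against day 3 the real split called 0 and the highest other 5, so all 10 of the splits gave as many. Over the 5 days 1 of 40 drawn groupings, the real one, reached 19158, and the highest other called 9199. That share lies under 0.05, but 40 groupings cannot give a smaller one, so a chance result of the grouping is unlikely there and not excluded.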

Other observations

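The neighbour test and the day 6 course were chosen after the data had been seen, with bounds set before their values were computed; the tests of a label swap, of day 3 stage tissue and of depth were chosen after the day 6 correlations had been seen, and the regions after their values.

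Several further regions held runs of neighbouring models that changed in the same direction. On scaffold526.0, 4 models between 20152 and 81318 were lower at day 9 by log2 changes from -4.66 to -2.18, and 3 of them were called lower at day 12, with a median of -6.83 over the 4; at day 9, 3 of the 4 were called without day 0 replicate 1. On scaffold126.0, 4 models between 208106 and 239473 were lower at day 9 with a median of -3.68, and 2, 3 and 3 of them were also called lower at day 3, day 6 and day 12. On scaffold3.0, 4 models between 2189915 and 2218871, on both strands, were lower at day 9 and at day 12 with medians of -2.96 and -2.71; all 4 were called at day 9 in each fit that left out a library, and 3 or 4 were at day 12. On scaffold436.0, 4 models between 48754 and 290702 were higher at day 9 with a median of 2.24, and 3 were called higher on each of the other days; 3 were called at day 9 without day 9 replicate 2. On scaffold241.0, 10 models are listed between 457076 and 578068 and 4 were tested. These 4, all on the minus strand, were lower at day 9 with a median of -2.32. Of them 1 was called lower at day 12 and none at day 3 or day 6. These 4, and those of scaffold126.0, were called at day 9 in each fit that left out a library. In all, 21 runs of at least 4 neighbouring models changed 2-fold in the same direction at day 9, 8 at day 12, 3 at day 6 and 0 at day 3. These counts were not set against shuffled order. More runs arise where more models change, and 6784, 3571, 1570 and 1209 models were called at 2-fold or more on those days. Like-changed neighbours exceeded shuffled order least at day 9, by a ratio of 1.21. With a library left out in turn, the runs that kept every call numbered 14 to 16 of 21 at day 9 (fewest without day 0 replicate 3), 3 to 7 of 8 at day 12 (fewest without day 0 replicate 2, day 12 replicate 1 or day 12 replicate 3, and 4 without day 0 replicate 3 or day 12 replicate 2) and 0 to 3 of 3 at day 6 (0 without any 1 of the day 0 libraries and 1 without day 6 replicate 3). With the length trend removed, 15 of 21, 8 of 8 and 3 of 3 did.

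Changed models lay next to each other on the scaffolds more often than in shuffled order. Neighbours that both changed at least 2-fold in the same direction were 3.49, 3.11, 1.21 and 2.23 times as frequent as in 1000 shuffles at day 3, 6, 9 and 12 (permutation p = 0.000999 each, the smallest that these shuffles can give, adjusted p = 0.00133). Overlapping models that share reads are argued against as the main source, since only 35 of the 27662 neighbours overlap. These held 0, 0, 5 and 0 of the 84, 127, 945 and 464 like-changed neighbours at day 3, 6, 9 and 12. The 5 at day 9 were 5.165 times the shuffled mean (permutation test, adjusted p = 0.00609). Neighbours at least 1000 bases apart gave ratios of 3.50, 3.28, 1.21 and 2.225 on the 4 days. Near-identical tandem copies that share reads remain open: same-strand neighbours gave 4.35, 4.28, 1.39 and 2.60 on the 4 days and opposite-strand neighbours 2.68, 1.87, 1.02 and 1.836, the day 9 value within the range of the shuffles (permutation p = 0.329), and sequences were not used here. Joint regulation of neighbouring genes stays open as a hypothesis that was not tested.

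The day 6 libraries differed more from each other than those of other days. Each day 3 library correlated better with its day 3 partners than with day 6 replicates 1 and 3, by a margin of at least 0.0323. No day 3 library thus lay nearer those replicates. This cannot decide on a swap of labels between day 3 and day 6. Day 6 replicate 1 itself had a mean correlation of 0.9466 with the day 3 libraries and 0.9434 with its day 6 partners. Lower depth is argued against for replicate 3, which had the most counts of the 3, 17319407, and for replicate 1, since a library of day 9 with fewer counts correlated with its partners at 0.9715, above each day 6 library. Day 6 replicate 2 may be a library of day 3 stage tissue, because its mean correlation with the day 3 libraries, 0.975, lay within the 0.972 to 0.977 found among them. Whether replicates 1 and 3 lay further along the course cannot be told apart from other differences, since the directions to days 9 and 12 took up 32.2% and 22.48% of their squared deviation from day 3, and the labels give no sampling stage beyond the day.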
